A study of Homo sapiens with 12 samples.

How the data were processed

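Gene expression had been measured by RNA sequencing in 12 libraries from 2 human cell lines, MUTZ-1 and SKM-1, which the labels describe as cells of myelodysplastic syndrome, a group of clonal disorders of blood formation. In each line, cells with a control short hairpin RNA (shRNA) and cells with an shRNA against NUDT21 formed 2 groups of 3 libraries. NUDT21 encodes the small subunit of cleavage factor Im (CFIm), a complex that binds nascent transcripts upstream of poly(A) sites and takes part in the choice of the 3' end. Lines, groups and replicate numbers were taken from the sample titles, since the series' own description gives the name MUTZ-1 for both of the lines at their first mention. The identity of the lines was not tested here. Per the labels' protocols, total RNA was isolated with TRIzol and libraries were made with the TruSeq Stranded mRNA kit, which selects polyadenylated RNA and keeps the strand. The replicates are separate samples in the labels, but nothing says that they came from separate cultures, so that p-values measure only the spread between these samples, which may be technical.

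The deposited table of counts holds whole numbers of reads per gene for 17518 genes and was used as deposited. The submitters' processing notes name fastp, HISAT2, HTSeq and the genome build GRCh38, without versions. The gene annotation, the strand setting of HTSeq and its treatment of reads with several matches are not given in the sources used here. Reads of near-identical gene copies, such as EIF3C and EIF3CL, U2AF1, the globins HBG1 and HBG2 or the replication-dependent histone genes, could be split or dropped in counting, and values of such genes are uncertain. Genes that overlap on opposite strands could share reads if strand was not used. Counts per gene do not show which poly(A) site was used. A deposited table of FPKM values, per the file headers from the same libraries, was used for 2 alternatives only. For the 17090 genes with a usable value, FPKM equalled the count divided by the library's total and by a length per gene that differed between libraries by at most 4.49e-07 of its value.

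Total counts per library ran from 15843012 to 18426619, and the gene with the most counts in every library, EEF1A1, took 0.839% to 1.23% of them. Replicates of a group differed by more than sampling noise, with chi-square per degree of freedom between 1.66 and 2.25 over 11173 to 12973 genes with at least 20 counts, so no library was taken for a copy of another.

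The filterByExpr function of edgeR 4.0.16 in R 4.3.3, run on the 4 groups, kept 13625 genes. The counts were scaled with trimmed means of M values (TMM, factors 0.959 to 1.06), and edgeR's quasi-likelihood test with robust shrinkage was run in 1 fit of all 12 libraries with a mean per group, which left 8 residual degrees of freedom. The biological coefficient of variation was 2.44%. The fit gave the knockdown effect in MUTZ-1, the knockdown effect in SKM-1, the difference between these effects (MUTZ-1 minus SKM-1) and control MUTZ-1 against control SKM-1. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene is said to have changed at an adjusted p under 0.05. Counts of genes changed at least 2-fold are given as well. Levels are given in CPM, counts relative to the library total, after TMM scaling, as mean ± SD over 3 libraries. Log2 fold changes carry their standard error (SE), obtained as the size of the log2 fold change divided by the square root of the F statistic. Where a group held no count, the fold is given as a lower bound from a floor of 3 counts over the group, on the same TMM scale, and with 1 to 3 counts as a ratio with a 95% interval. These floors and intervals cover counting error only.

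Before the data were examined, 29 gene lists were fixed, covering 3' end processing, mutated genes of the disease, the cell cycle, p53, ribosomes, metabolism, stress, interferon and antigen presentation, and markers of blood lineages, fibroblasts and epithelia. Each was tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, which compares a list with all other genes, and p-values were adjusted over the lists of a comparison. The same test with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction, were alternatives. As given further below, some splits with mixed labels gave as many called lists as the real labels, except for the knockdown in MUTZ-1. Adjusted p-values of camera in the other comparisons may therefore overstate the evidence. A list of 13 mRNAs encoded by mitochondrial DNA had 0 members in the table, which left 28 lists. Named genes followed a rule fixed at the same time. They are, per comparison and direction, the 10 genes with the largest log2 fold change among changed genes with a mean of at least 5 CPM and no overlap between the groups. Further genes are the 10 changed in 1 direction in both lines with the largest smaller change; the 5 with the smallest p for the difference between lines, up to 4 members with the smallest p per list, and NUDT21 with its CFIm partners CPSF6 and CPSF7. Genes named outside this rule are marked as chosen after their values were seen. Some genes that met the rule are not reported here.

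The steps were tested on simulated counts drawn from the means and totals of these libraries with 50 genes changed at each fold size. At 1.2-fold, 74% of changed genes were recovered for MUTZ-1 (13499 genes), 66% for SKM-1 (13444 genes), 82% for the control lines (13509 genes) and 50 percent for the difference between lines (13409 genes). At 1.5-fold these shares were 98%, 96%, 100 percent and 90 percent. Of the genes called, 7.89%, 6.51%, 5.36% and 3.16% were unchanged ones, above the nominal 5% in all but the last. Most genes were unchanged in the simulation, while in the data 49.0% were called in MUTZ-1 and 84.4% in SKM-1. Scaling under so many changes was not tested, so these shares may not hold for the data.

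Alternatives fixed beforehand were size factors by relative log expression (RLE), library totals alone, a stricter filter of at least 50 counts in 3 libraries, no filter, an adjusted p under 0.01, DESeq2 1.42.0, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a correction for gene length, only the 6 libraries compared. Others were a block for the replicate number and leaving out each library in turn. A minimum mean of 1 CPM was added after the data were seen. The first version of the length correction shifted all values of a library, and it was replaced by 1 centred on each library after its first values had been seen. Positions come from the GENCODE release 29 annotation of GRCh38, where 13317 of the tested genes (97.7%) were found. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3.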

Results

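The comparisons ask how lowering NUDT21 changes the mRNA levels of MUTZ-1 and SKM-1 cells. The 12 libraries fell into 4 groups of 3, control and NUDT21 shRNA in each line, with 15843012 to 18426619 counts per library. In a principal component analysis, the first component (81.9% of the variance) separated the lines, the second (15.2%) separated SKM-1 knockdown from SKM-1 control, and the third (1.24%) separated MUTZ-1 knockdown from MUTZ-1 control.

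NUDT21 (chromosome 16, positions 56429133 to 56452199, minus strand, GRCh38) was lower in every knockdown library than in every control library. Its level was 301, 297 and 301 CPM in the MUTZ-1 control libraries and 135, 136 and 142 CPM after knockdown, which left 46.1% (95% interval 44.4 to 47.9; log2 fold change -1.12 ± 0.03 SE, adjusted p = 1.01e-94). In SKM-1 it was 322, 336 and 344 CPM in the control libraries and 131, 132 and 129 CPM after knockdown, which left 39.2% (37.7 to 40.7; -1.35 ± 0.03 SE, adjusted p = 4.87e-112). The larger subunits of CFIm moved the other way or apart. CPSF6 (chromosome 12, positions 69239537 to 69274358, plus strand) rose from 308 ± 7.98 to 416 ± 7.42 CPM in MUTZ-1 and from 216 ± 7.37 to 285 ± 6.42 CPM in SKM-1 (log2 fold changes 0.44 ± 0.02 and 0.40 ± 0.03; adjusted p = 6.79e-42 and 1.49e-35). CPSF7 (chromosome 11, positions 61402641 to 61430031, minus strand) fell from 272 ± 8.16 to 239 ± 4.28 CPM in MUTZ-1 and rose from 114 ± 2.30 to 197 ± 3.79 CPM in SKM-1 (-0.18 ± 0.03 and 0.79 ± 0.03; adjusted p = 9.23e-10 and 2.33e-65).

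**Figure D1:**
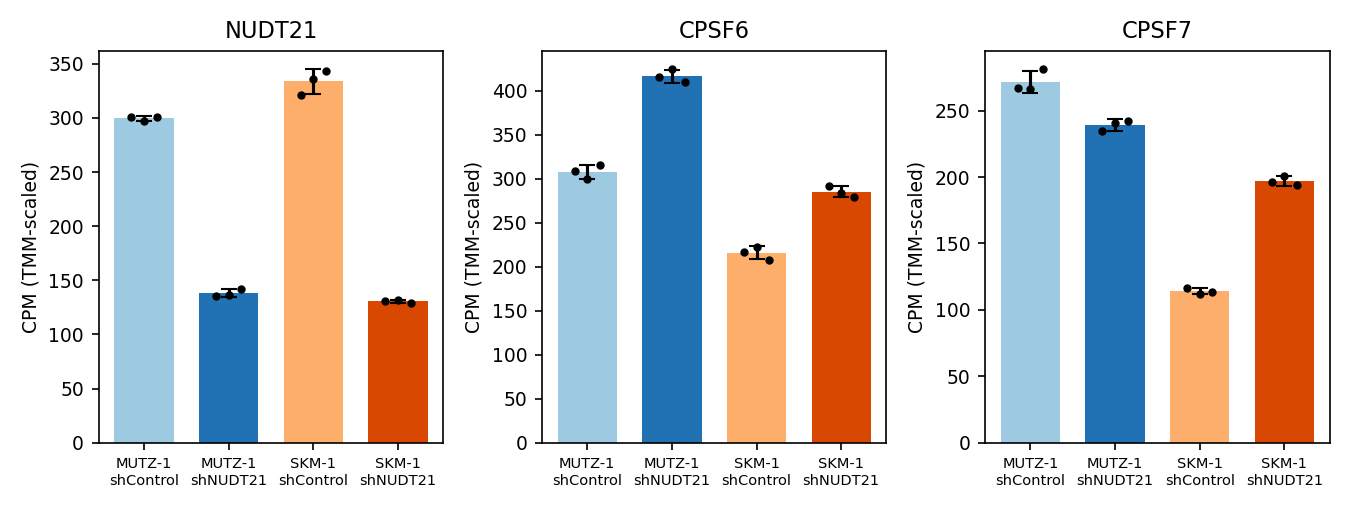
Level of NUDT21, CPSF6 and CPSF7 in CPM after TMM scaling in the 4 groups, with bars for means, points for the 3 libraries of a group and error bars for the SD. NUDT21 lies at 138 CPM in knockdown MUTZ-1 and 131 CPM in knockdown SKM-1, below every control library.

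In MUTZ-1, genes of the type I interferon response fell after NUDT21 knockdown. Of 27 members tested, 23 fell, 18 of them at least 2-fold, and 1 rose (adjusted over the list alone, 24 fell and 1 rose). MX1, an antiviral GTPase, fell from 229 ± 3.91 to 5.87 ± 0.347 CPM (log2 fold change -5.28 ± 0.06 SE, n = 3 per group). IFI44L fell from 94.0 ± 2.79 to 0.524 ± 0.0564 CPM (-7.47 ± 0.13). OAS2, which makes oligoadenylates on sensing double-stranded RNA, fell from 149 ± 1.53 to 57.0 ± 2.61 CPM. IFI44, EPSTI1, IRF7 and SLFN11, all inducible by interferon, were also among the 10 largest falls (from 33.5 to 1.99, from 15.3 to 1.19, from 11.2 to 1.36 and from 14.1 to 1.77 CPM). The highest adjusted p among these 7 genes was 6.04e-33. The list's median log2 change was -1.46, or -1.38 over the 23 members at 1 CPM or more (camera, adjusted p = 3.02e-20; adjusted p = 1.46e-04 with an estimated correlation).

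Antigen presentation genes also fell in MUTZ-1. Of the 15 MHC class I and antigen processing genes, 12 fell and 2 rose, both over all genes and adjusted over the list alone. HLA-B fell from 581 ± 9.72 to 438 ± 5.04 CPM, its light chain B2M from 908 to 767 CPM. The peptide transporter genes TAP1 and TAP2 fell from 68.4 to 49.2 and from 167 to 115 CPM (camera, adjusted p = 1.11e-04; adjusted p = 0.0121 with an estimated correlation). Of 12 MHC class II genes, 8 fell and 0 rose, also adjusted over the list alone, among them HLA-DRA from 253 ± 6.61 to 184 ± 3.92 CPM and the invariant chain CD74 from 1312 ± 14.4 to 1056 ± 16.2 CPM. That list passed camera with adjusted p = 0.0278, but not with an estimated correlation (adjusted p = 0.308 with an estimated correlation) nor without MUTZ-1 control replicate 2 (adjusted p = 0.0595). HLA-B, HLA-DRA and CD74 each lost their call in 1 alternative, log2(FPKM + 0.1) (adjusted p = 0.381, 0.209 and 0.564).

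Genes of ribosome assembly and of sterol synthesis fell in MUTZ-1 as well. Of 25 ribosome biogenesis and MYC target genes, 23 fell and 1 rose (24 and 1 adjusted over the list alone). The nucleolar protein gene NCL fell from 2155 ± 42.1 to 1583 ± 16.1 CPM and the rRNA methyltransferase gene NOP2 from 191 ± 6.82 to 124 ± 2.24 CPM. ODC1, which starts polyamine synthesis, fell from 930.3 to 681 CPM and LDHA from 1671 to 1157 CPM (camera, adjusted p = 6.02e-25; adjusted p = 7.32e-04 with an estimated correlation). Of 23 cholesterol synthesis genes, 19 fell and 1 rose, also adjusted over the list alone. HMGCS1, an enzyme early in the pathway, fell from 232 ± 4.21 to 128 ± 5.52 CPM. SQLE fell from 175 to 117 CPM and FDFT1 from 412 to 306 CPM (camera, adjusted p = 3.17e-12; adjusted p = 0.00145 with an estimated correlation). Cytosolic ribosomal protein genes moved the other way by small amounts. Of 28, 19 rose and 3 fell, also adjusted over the list alone. RPL11 rose from 771 ± 13.2 to 925 ± 21.3 CPM and RPL5 from 976 ± 13.9 to 1149 ± 33.3 CPM (camera, adjusted p = 1.41e-04, but adjusted p = 0.514 with an estimated correlation).

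Mitosis genes fell by small amounts in MUTZ-1, 16 of 25, while 5 rose (17 and 5 adjusted over the list alone). PLK1, BIRC5 and UBE2C fell from 293 to 241, from 148 to 116 and from 154 to 119 CPM, and CENPF, a kinetochore protein gene, rose from 395 to 502 CPM. The list passed camera with adjusted p = 0.0125, but not with an estimated correlation (adjusted p = 0.0706 with an estimated correlation) nor without MUTZ-1 knockdown replicate 2 (adjusted p = 0.0501). Of 26 glycolysis and hypoxia genes, 11 fell, with TPI1 from 949 to 738 CPM and GPI from 519.6 to 409 CPM, and 4 rose, with the enolase gene ENO2 from 0.324 to 3.54 CPM, also adjusted over the list alone. Its test and its median (-0.07) were negative and its mean (0.03) positive (camera, adjusted p = 0.0201; adjusted p = 0.190 with an estimated correlation).

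The largest rises in MUTZ-1 included 2 genes of receptor tyrosine phosphatases that are neighbours on chromosome 12, PTPRB and PTPRR. PTPRB rose from 1.15 ± 0.349 to 12.2 ± 0.555 CPM, and PTPRR from 4.04 to 42.2 CPM (log2 fold change 3.38 ± 0.10 SE). ABCG1, a cholesterol exporter, rose from 11.4 ± 0.615 to 67.1 ± 0.864 CPM. HBEGF, a ligand of the EGF receptor, rose from 8.19 ± 0.620 to 37.4 ± 1.09 CPM, and KIAA1217 from 11.5 to 41.1 CPM. CYRIA, CTTN (cortactin), VEGFD, GABRR2 and the ETS factor gene ETV5 made up the rest of the 10, and the highest adjusted p among them was 8.77e-20. ETV5 belongs to the ERK output genes, of which 7 of 18 rose and 1 fell, also adjusted over the list alone. EGR1 rose from 2.81 to 7.78 CPM, without a call for the list (camera, adjusted p = 0.0919). Beside interferon genes, the largest falls were of the chemokine gene CCL22, from 22.3 to 0.240 CPM, and of CELF2, from 14.3 to 1.51 CPM. MS4A1, which encodes the B-cell antigen CD20, fell from 187 ± 3.04 to 23.2 ± 0.782 CPM, and EIF3CL fell from 81.3 ± 55.0 to 3.02 ± 0.361 CPM. EIF3CL shares most of its sequence with EIF3C, and its libraries scattered widely. Its call (adjusted p = 0.0187) was lost when control replicate 1 or any of the 3 knockdown replicates was left out (highest adjusted p = 0.0620). The transferrin receptor gene TFRC fell from 736 ± 12.2 to 291 ± 2.91 CPM, and CTSS, a lysosomal protease gene among the monocyte markers, from 82.8 to 34.4 CPM.

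The other 20 lists were not called in MUTZ-1 (camera, adjusted p between 0.0919 and 0.974). Among p53 target genes 11 of 23 rose and 6 fell, also adjusted over the list alone, with SESN1 from 49.8 to 84.9 CPM, TP53INP1 from 11.2 to 25.4 CPM and AEN from 97.7 to 59.0 CPM. Of 15 genes known to have poly(A) sites that depend on NUDT21, 4 rose, among them the growth factor receptor gene IGF1R from 80.8 to 101 CPM, and 6 fell, among them PSMB2 from 341 to 304 CPM, with the same counts adjusted over the list alone. In the BCL2 family, BMF, which promotes cell death, rose from 19.8 to 43.6 CPM and CYCS fell from 493 to 374 CPM, and 8 of 26 members rose and 10 fell, also adjusted over the list alone. B-lineage markers went both ways, 7 of 20 up and 7 down (9 and 7 adjusted over the list alone), with RAG2 from 37.4 to 61.8 CPM and FCRLA from 537 to 457 CPM. FCRLA lost its call with log2(FPKM + 0.1) (adjusted p = 0.195).

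By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3326 genes rose and 3354 fell in MUTZ-1 out of 13625, of which 424 and 223 changed at least 2-fold. Most of these larger changes were of genes with few counts, and among the 9713 genes with a mean of at least 5 CPM, 87 rose and 34 fell that far. The share of rises among the calls depended on the scaling. It was 49.8% with TMM, 60.7% with library totals alone (4056 up, 2626 down), 61.1% with log2(FPKM + 1) (3817 up, 2426 down) and 61.2% with log2(FPKM + 0.1) (3743 up, 2372 down).

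All SKM-1 changes, here and in the comparison of the lines, are differences between the SKM-1 control and knockdown libraries. As given further below, medians per chromosome shifted between these groups, and an effect of NUDT21 was not separated from a difference between subclones. In SKM-1, erythroid markers rose after knockdown, 19 of 20 tested, 17 of them at least 2-fold, and 0 fell, also adjusted over the list alone. GATA1, the master transcription factor of red cell formation, rose from 64.0 ± 1.56 to 270.1 ± 8.86 CPM (log2 fold change 2.08 ± 0.04 SE, n = 3 per group), and TFRC from 424 ± 8.95 to 1462 ± 21.3 CPM (1.79 ± 0.02). ANK1, a gene of the red cell skeleton, rose from 129 ± 2.33 to 441 ± 3.20 CPM. The median log2 change of the list was 1.85 (camera, adjusted p = 1.03e-07; adjusted p = 0.00562 with an estimated correlation). In the megakaryocyte list, not called (camera, adjusted p = 0.351), NFE2 and GP1BB rose from 73.1 to 261 and from 30.7 to 124 CPM, and 5 of 10 members rose and 2 fell, also adjusted over the list alone. Epithelial markers moved with the erythroid genes. Of 6 tested, 5 rose and 0 fell, also adjusted over the list alone. KRT19 rose from 27.7 ± 0.962 to 131 ± 0.657 CPM and EPCAM from 14.1 ± 1.73 to 75.4 ± 1.10 CPM. KRT8 rose from 192 to 334 CPM and KRT18 from 144 to 239 CPM (camera, adjusted p = 0.00871; adjusted p = 0.0828 with an estimated correlation). KRT8 lost its call with log2(FPKM + 0.1) (adjusted p = 0.0828).

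DNA replication genes rose in SKM-1, 19 of 26, and 3 fell (20 and 3 adjusted over the list alone). CDC45 rose from 148 ± 6.17 to 415 ± 6.86 CPM. The helicase subunit genes MCM6, MCM7 and MCM4 rose from 131 to 315, from 395 to 787 and from 337 to 584 CPM (camera, adjusted p = 2.48e-04; adjusted p = 0.0200 with an estimated correlation). Ribosome biogenesis and MYC target genes rose as well, 22 of 25, and 3 fell, also adjusted over the list alone. NOP58, RRP12 and BOP1 rose from 87.0 to 186, from 47.4 to 115 and from 124 to 228 CPM. MYC itself fell from 2140.3 ± 43.0 to 465 ± 6.05 CPM (camera, adjusted p = 2.48e-04, but adjusted p = 0.109 with an estimated correlation). Cholesterol synthesis genes fell, 19 of 23, and 3 rose, also adjusted over the list alone. SREBF2, the transcription factor of the pathway, fell from 526 ± 9.16 to 209 ± 2.74 CPM and MSMO1 from 115 ± 3.03 to 25.7 ± 1.16 CPM. FDFT1 fell from 472 to 292 CPM and FDPS from 359.8 to 220.0 CPM (camera, adjusted p = 0.00194, but adjusted p = 0.0733 with an estimated correlation).

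Single genes of other lists changed by large amounts in SKM-1 without a call for the list. Among stem and progenitor cell genes, 6 of 16 rose, including MYB from 56.7 ± 2.37 to 281 ± 1.70 CPM and GATA2 from 59.8 ± 1.58 to 195 ± 0.979 CPM. In the same list 10 fell, including ERG from 60.4 ± 1.83 to 2.13 ± 0.645 CPM and MEIS1 from 65.0 ± 0.622 to 10.7 ± 0.712 CPM, also adjusted over the list alone (camera, adjusted p = 0.893). CD36, a fatty acid receptor listed among monocyte markers, fell from 917 to 26.5 CPM, while 8 of the 12 markers in that list rose and 3 fell, also adjusted over the list alone. PHGDH, the first enzyme of serine synthesis, fell from 390.1 ± 1.63 to 26.1 ± 1.98 CPM. UBE2C, a mitotic ubiquitin-conjugating enzyme, fell from 92.2 ± 1.31 to 4.33 ± 0.897 CPM while 13 of the 25 mitosis genes rose and 7 fell, also adjusted over the list alone. TIGAR, a p53 target, fell from 25.7 to 1.91 CPM, while 11 of the 23 p53 targets rose and 11 fell, also adjusted over the list alone. TIMP2, an inhibitor of metalloproteases with a known NUDT21-dependent poly(A) site, fell from 141 to 4.11 CPM. Of the 15 genes with such sites 6 rose, among them PSMB2 from 184 to 378 CPM, and 7 fell, with the same counts adjusted over the list alone. Hexokinase gene HK1 rose from 261 to 1146 CPM while PGK1 fell from 1180.1 to 472 CPM and PKM fell from 1558 to 856 CPM. Of the glycolysis list 17 of 26 genes fell and 6 rose, also adjusted over the list alone (camera, adjusted p = 0.0550; 0.0470 with library totals alone).

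The largest rises in SKM-1 were of genes at low levels in the control libraries. LMO3, a LIM-domain cofactor, rose from 0.0736 ± 0.0638 to 21.3 ± 2.70 CPM, and NTS, the precursor of neurotensin, from 0.226 ± 0.151 to 34.1 ± 2.67 CPM. ARHGAP15 rose from 2.17 ± 0.812 to 50.5 ± 1.36 CPM, the neurofilament gene NEFH from 4.23 ± 0.412 to 64.1 ± 1.36 CPM and the water channel gene AQP1 from 1.60 ± 0.728 to 23.5 ± 0.815 CPM. The largest falls went close to zero. COL13A1, a collagen gene, fell from 10.5 ± 0.776 CPM to no count, at least 171-fold. PRSS56, SULF1, SEMA5A and the WNT inhibitor gene WIF1 fell from 81.1 to 0.246, from 46.1 to 0.144, from 85.7 to 0.350 and from 26.2 to 0.185 CPM. The highest adjusted p among the 20 genes with the largest changes was 8.79e-39. In all, 5735 genes rose and 5765 fell of 13625, 1716 and 3064 of them at least 2-fold. Among the 10748 genes with at least 5 CPM, the SD of the log2 fold changes was 1.48, against 0.34 among the 9713 such genes in MUTZ-1.

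**Figure D2:**
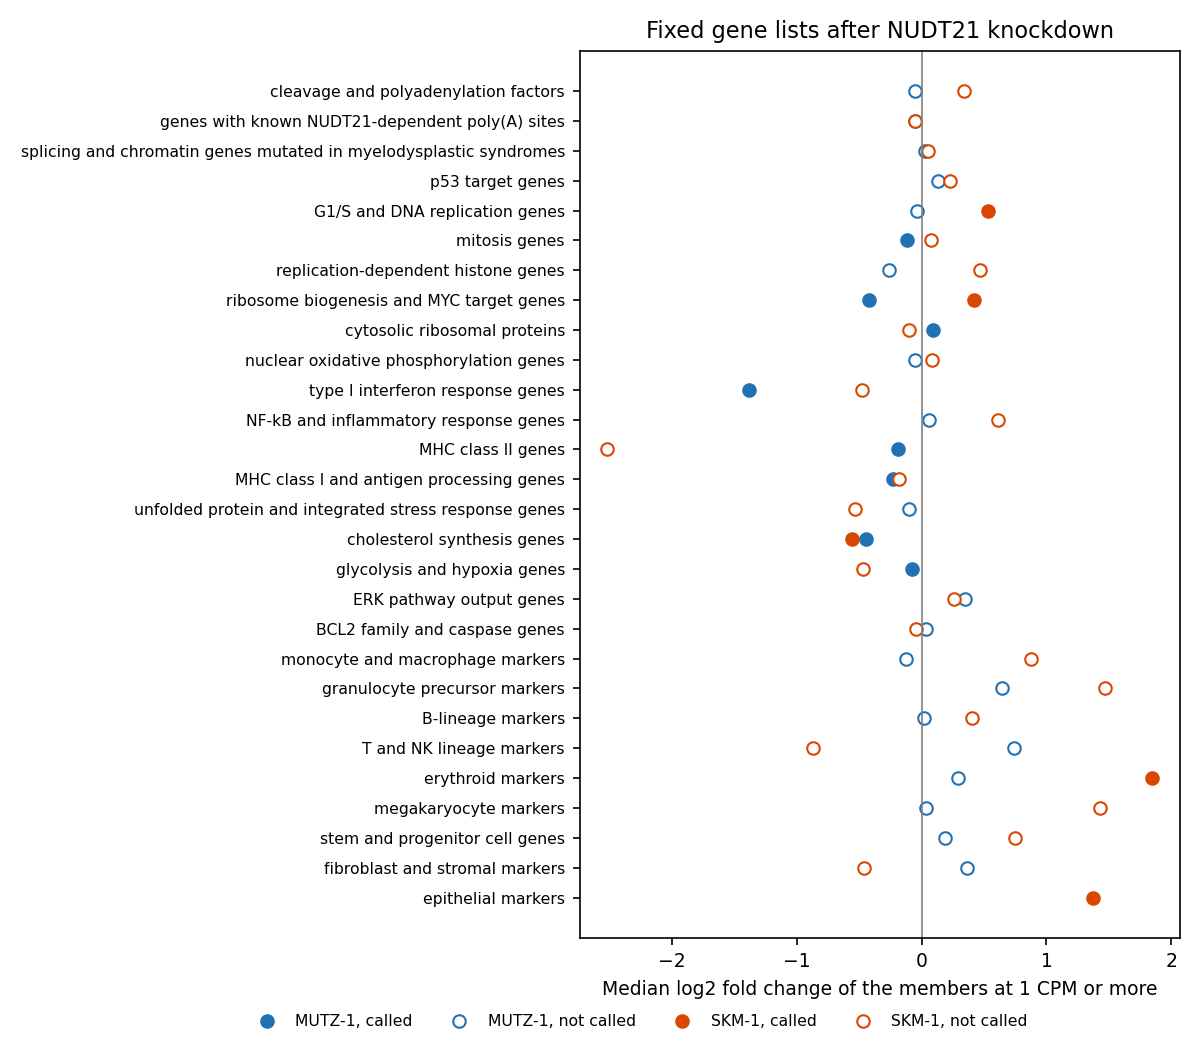
Median log2 fold change after knockdown over the members at 1 CPM or more of each of the 28 lists, in MUTZ-1 and in SKM-1, with filled points for lists called by camera with the preset correlation. No epithelial marker reached that level as a mean over the 6 MUTZ-1 libraries, and the lowest and highest medians are those of MHC class II genes (-2.52, 2 members) and erythroid markers (1.85) in SKM-1.

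Changes after knockdown differed between the lines for many genes. Those of DNA replication genes and ribosome biogenesis genes were more negative in MUTZ-1 than in SKM-1, 23 of 26 and 23 of 25 members (also adjusted over the list alone). The median differences were -0.61 and -0.89 on the log2 scale (camera, adjusted p = 7.29e-06 and 5.88e-10; adjusted p = 0.0141 and 0.0200 with an estimated correlation). TFRC fell in MUTZ-1 and rose in SKM-1 (difference -3.12 ± 0.03 SE), and so did the chaperone gene HSPA8 (-2.20 ± 0.02), the RNA helicase gene DDX21 (-1.95 ± 0.03) and ACTB (-1.48 ± 0.02). The changes of UCHL1, PHGDH, NREP and MYC were more positive in MUTZ-1, where PHGDH stood at 481 ± 17.5 CPM before and 495 ± 5.73 CPM after knockdown. Of the 13625 genes, 4958 had a more positive change in MUTZ-1 and 4848 in SKM-1. NUDT21 itself differed by 0.23 (adjusted p = 5.36e-08), and CPSF6 by 0.03 (adjusted p = 0.400). With the correction for gene length the CPSF6 difference was -0.083 (adjusted p = 0.0216). Replacing TMM with library totals shifted the median of all genes by 0.13 in this comparison and by -0.14 between the control lines, and with log2(FPKM + 1) by 0.12 and -0.12.

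Fewer genes changed in the same direction in both lines than independent lists would share. In both lines 1052 genes rose, where 1400.0 would be shared by independent lists, and 897 fell, where 1419 would be. Opposite changes were more frequent, 1778 genes up in MUTZ-1 and down in SKM-1 (1407 by independence, exact hypergeometric test over genes, p = 2.31e-50) and 2038 the other way (1412, p = 2.36e-139). At 2-fold or more, 80 genes rose in both (53.4 by independence, exact hypergeometric test, p = 1.17e-04) and 82 fell in both (50.1, p = 7.88e-07). At that size opposite changes were also more frequent than by independence. The exact hypergeometric test gave p = 1.86e-19 for 177 genes up in MUTZ-1 and down in SKM-1 (95.3 by independence) and p = 1.34e-05 for 51 the other way (28.1). Every pair of directions thus exceeded independence at that size, which sets neither a shared nor an opposite response apart. All these hypergeometric tests treat genes as independent draws, which they are not, so their p-values are descriptive. PTPRR rose from 4.04 to 42.2 CPM in MUTZ-1 and from 3.66 to 18.7 CPM in SKM-1, and SAMD5 from 0.690 to 3.38 and from 8.70 to 38.4 CPM. The calcium channel gene RYR2 fell in both lines (log2 fold changes -7.26 ± 0.44 and -5.41 ± 0.13 SE). In MUTZ-1 RYR2 did not meet the rule for the largest falls, a mean of at least 5 CPM without overlap of the groups, and the size of its fall there is uncertain. IFI44 and CCL22 fell in SKM-1 from low levels, from 2.39 to 0.0617 and from 0.788 to 0.0418 CPM. DDX60, an interferon-induced helicase gene, fell from 2.63 ± 0.246 CPM to no count in MUTZ-1, at least 43.5-fold. It fell from 1.37 to 0.0399 CPM in SKM-1 (2 counts left, ratio 33.2, 95% interval 8.87 to 279). Most other genes chosen for a shared change were at trace levels in MUTZ-1. Across the 9041 genes with at least 5 CPM in both lines, which are not independent replicates, Pearson's r of the log2 fold changes was -0.27 and Spearman's rho -0.29.

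The control libraries describe the lines without knockdown, under the line names of the sample titles. MUTZ-1 had the markers of B-lineage cells. All 20 B-lineage markers were higher in MUTZ-1 than in SKM-1, also adjusted over the list alone. Among them were the B-cell receptor gene CD79B (630.0 ± 15.5 against 0.672 ± 0.301 CPM) and the transcriptional coactivator gene POU2AF1 (534 ± 7.20 against 0.559 ± 0.193 CPM). FCRLA (537 ± 7.91 against 0.429 ± 0.0901 CPM) and the kinase gene BLK (363 ± 3.02 against 0.562 ± 0.164 CPM) were further members. The 12 MHC class II genes were all higher as well, with HLA-DRA at 253 ± 6.61 against 0.317 ± 0.0328 CPM and their transactivator CIITA at 111 ± 3.49 against 0.131 ± 0.0358 CPM. So were 12 of 15 class I genes, with HLA-B at 581 ± 9.72 against 2.42 ± 0.350 CPM, and 19 of 27 interferon response genes, with MX1 at 229 ± 3.91 against 0.130 ± 0.0284 CPM, with the same counts adjusted over the list alone. Among p53 targets, CDKN1A and MDM2 stood at 123 ± 2.37 against 5.75 ± 0.677 CPM and 361 ± 9.58 against 66.9 ± 2.27 CPM, with no call for the list (camera, adjusted p = 0.115). LRRC34, LY86 and HLA-DQA1 had no count in SKM-1 control and were at least 529-fold, 479.8-fold and 464-fold higher in MUTZ-1.

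Control SKM-1 had the markers of red cell precursors. Of 20 erythroid markers tested, 18 were lower and 1 higher in MUTZ-1 than in SKM-1, with GATA1 at 0.0566 ± 0.0566 against 64.0 ± 1.56 CPM and ANK1 at 12.1 ± 0.803 against 129 ± 2.33 CPM. In control SKM-1 19 of the 20 reached 1 CPM, against 4 in control MUTZ-1. All 6 epithelial markers tested were lower in MUTZ-1, with KRT8 at 0.171 ± 0.148 against 192 ± 4.10 CPM and KRT18 at 0.0754 ± 0.0864 against 144 ± 2.24 CPM. So were 12 of 13 fibroblast and stromal markers, with the fibronectin gene FN1 at 0.174 ± 0.0630 against 61.3 ± 3.72 CPM. ERK output genes (15 of 18 lower in MUTZ-1, ETV5 at 1.58 ± 0.0428 against 114 ± 3.05 CPM) were lower too. So were cholesterol synthesis genes (22 of 23) and replication-dependent histone genes (16 of 18, H1-2 at 4.12 ± 0.559 against 298 ± 2.98 CPM). These counts were the same adjusted over the list alone. Values of the histone genes are uncertain, as the libraries were selected for polyadenylated RNA and these genes have near-identical copies. SCML1, CPE and the transcription factor gene PRRX1 had no count in MUTZ-1 control, and were at least 2283-fold, 1627-fold and 1384-fold lower.

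Between the control lines, 5639 genes were higher and 6644 lower in MUTZ-1 out of 13625, 2189 and 4034 of them at least 2-fold. Camera called 8 lists higher in MUTZ-1 (adjusted p at most 0.00973), the 4 above and 4 more. The latter were DNA replication (23 of 26 higher, UHRF1 at 316 ± 1.55 against 74.5 ± 2.96 CPM), mitosis (17 of 25), ribosome biogenesis (22 of 25) and cleavage and polyadenylation factors (15 of 21, PAPOLA at 461 ± 9.31 against 211 ± 8.22 CPM), with the same counts adjusted over the list alone. It called 6 lists lower (adjusted p at most 0.00973). With an estimated correlation the fibroblast list was no longer called (adjusted p = 0.0621 with an estimated correlation), and the other 13 were (adjusted p at most 0.0468).

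**Figure D3:**
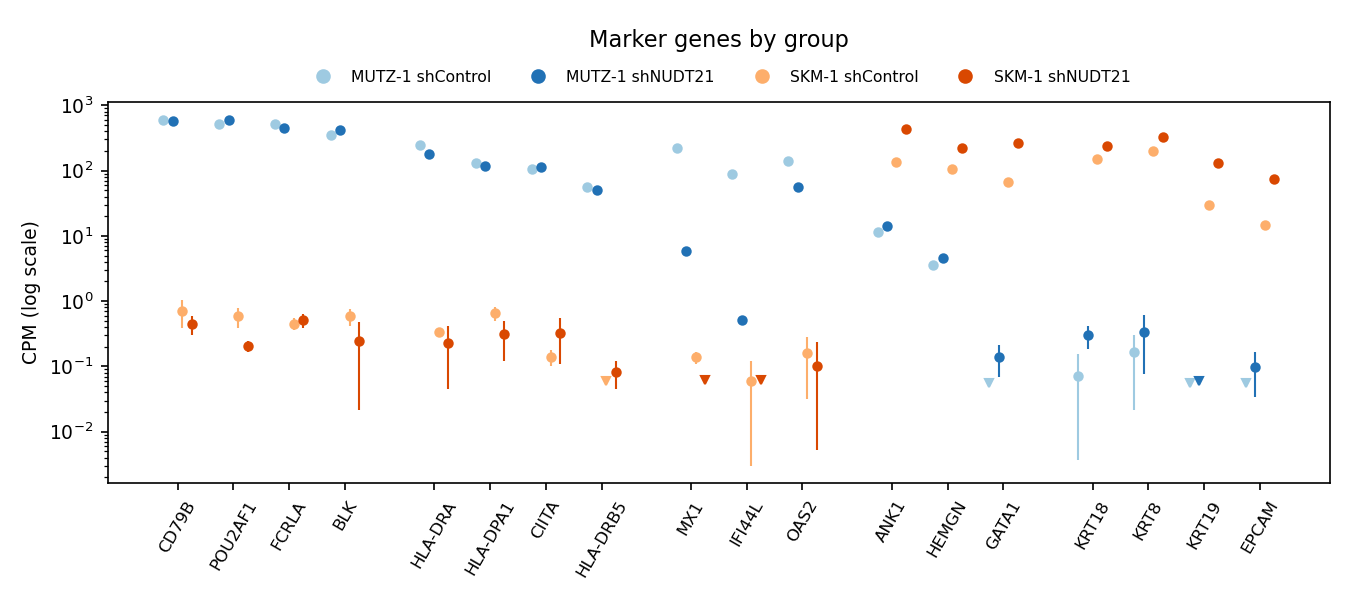
Level of 18 list members in CPM (log axis) in the 4 groups, with points for means of 3 libraries, bars for the SD and triangles for means at or below the level of 3 counts over the group, drawn there. B-lineage and MHC class II genes lie high in both MUTZ-1 groups, erythroid and epithelial genes in both SKM-1 groups, and the interferon genes MX1 and IFI44L in MUTZ-1 control.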

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

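The test of the difference between lines was planned, and the tests by mixed labels and the tests of explanations in this part were chosen after the results they bear on had been seen. The results given first differed between the lines by the test of the difference of the knockdown effects (MUTZ-1 minus SKM-1).

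By that test, 4958 genes had a more positive change in MUTZ-1 and 4848 in SKM-1. Log2 differences with their SE were positive for NUDT21 (0.23 ± 0.04), UCHL1 (4.50 ± 0.05), PHGDH (3.94 ± 0.04), NREP (5.99 ± 0.07) and MYC (2.26 ± 0.03). They were negative for TFRC (-3.12 ± 0.03), HSPA8 (-2.20 ± 0.02), DDX21 (-1.95 ± 0.03), ACTB (-1.48 ± 0.02) and PRKCB (-2.19 ± 0.04). The list medians were -0.61 for DNA replication genes and -0.89 for ribosome biogenesis and MYC target genes.

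Knockdown labels were also mixed within the lines in 100 drawn splits of 200, the real 1 included. Of these, 1, the real labelling itself, had as many as the real 9806 genes (highest other 8312). The 82 splits that mixed both lines called 0 genes, and the 11 that mixed SKM-1 alone called 33 to 57. Mixing puts a difference between groups into the spread within them, so few calls follow almost by construction. The count thus shows only that the labels match the groups into which the libraries fall. A chance difference between single cultures cannot be excluded, since the replicates may be technical. The high counts of other splits came from the 6 splits that kept the SKM-1 labels (7955 to 8312 genes). These splits still hold the whole difference between the SKM-1 groups, so they cannot tell a structure of the samples apart from the knockdown. For lists, 99 of the 100 splits called at least the real 2 (highest other 10), and chance cannot be excluded for that number. The splits that mixed both lines called 2 to 10 lists. For genes changed in the same direction in both lines, 1 split, again the real labelling, had as many as the real 1949 (highest other 0). Other splits of a single line called at most 1 gene, so none of them could share genes between the lines, and nothing is concluded from this count. Independent lists would share 1400.0 rising and 1419 falling genes.

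Within 1 comparison, 6 libraries make 10 splits, too few for a share under 0.05, and the real split is counted among them. For genes changed in MUTZ-1, 1 of the 10 splits gave as many, real 6680, highest other 1, and for lists 1 of the 10 splits gave as many, real 8, highest other 6. In SKM-1 the figures were for genes 1 of the 10 splits gave as many, real 11500, highest other 0, and for lists 6 of the 10 splits gave as many, real 5, highest other 7. Between control lines 1 of the 10 splits gave as many genes, real 12283, highest other 0. For lists 6 of the 10 splits gave as many, real 14, highest other 15. In SKM-1 and between control lines, wrong labels thus gave as many called lists, and chance cannot be excluded for these numbers. Camera's adjusted p-values for these comparisons and for the difference between lines may overstate the evidence.

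The SKM-1 groups differed at least 2-fold in 4780 genes, and the MUTZ-1 groups in 647. Scaling of the libraries is argued against by a count of 4753 or more with library totals or RLE. The knockdown of NUDT21 as the whole cause is argued against by medians per chromosome between -0.82 (chromosome 13) and 0.75 (chromosome 21), whose SD of 0.31 exceeded the median SD of 0.20 in 6757 shifts of the values along the genome (permutation p = 0.00547; in MUTZ-1 0.738). A candidate explanation is 2 cell populations in different shares. It needs 1 control to knockdown ratio for the genes of the growing population. Of 16 erythroid markers, 14 (87.5%) lay within 1.5 times their median ratio of 26.3%. So did 41.8% of the 416 genes at 20 CPM or more in the knockdown and under 0.5 CPM in MUTZ-1 control. These 416 genes include some of the markers but not those present in MUTZ-1, such as TFRC and ANK1, so the sets are unlike. A joint rise of the erythroid genes within the same cells would also give 1 ratio, so this check cannot tell the 2 apart. On the shrinking side, 239 of 575 genes at 20 CPM or more in SKM-1 control and under 0.5 CPM in MUTZ-1 control were left at under 10% of their control level, with a median of 3.24% among those (quartiles 2.42% and 4.41%). These 239 genes were picked for a level under 10%, so a low and narrow range follows in part from that choice and does not test the explanation. The 8 genes LMO3, NTS, MS4A4A, ARHGAP15, NEFH, AQP1, MS4A3 and MAGEB1 stood in control at 0.345% to 10.1% of their knockdown level, below what those markers show. For these genes a change of shares cannot be told apart from other causes, because most of them are among the 10 largest rises themselves and the markers could be expressed in both populations. Different subclones of the line, with the knockdown on top, stay open, and the biological effect of NUDT21 in SKM-1 was not separated from them.

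Interferon response genes fell in MUTZ-1, with a median log2 change of -1.46. Scaling of the libraries is argued against by a median of -1.41 with library totals or RLE size factors, whichever moved it more. Loss of cells of another type would take away the abundant transcripts that only those cells make. Of 7629 genes at 20 CPM or more in the control, only 10 fell at least 4-fold. Of these 5 were in the list and 5 outside it, CCL22, EIF3CL, MS4A1, PARP14 and RIPOR2. This argues against the loss of cells with many abundant genes of their own. Loss of a small or closely related population cannot be told apart, since transcripts shared with the remaining cells would hardly fall. Interferon signalling set off in the control cultures by the control shRNA or its vector cannot be told apart from an effect of the knockdown, since 0 groups were without an shRNA. An effect of lower NUDT21 on interferon signalling stays open and was not tested. The labels name no more than 1 shRNA against NUDT21 (sh1), so in either line other effects of that shRNA cannot be told apart from those of lower NUDT21.

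EIF3CL fell in MUTZ-1 from 81.3 ± 55.0 to 3.02 ± 0.361 CPM. Its copy EIF3C (chromosome 16, positions 28688558 to 28735730, plus strand) and EIF3CL (chromosome 16, positions 28379579 to 28403879, minus strand) may exchange reads, in which case their sum would stay level. The sum had a log2 ratio of -0.51 with an SE of 0.69 and ran from 35.1 to 166 CPM over the MUTZ-1 libraries, so reads shifting between the copies cannot be told apart from a fall, because the sums scatter too widely. That a change of the sum must exceed its spread was asked for only after the value had been seen. In SKM-1, knockdown replicate 3 had 96.5 CPM of EIF3CL and replicates 1 and 2 had 5.83 and 6.28 CPM.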

How the results depend on the processing

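All alternatives were fixed before the data were examined except the minimum mean of 1 CPM and the reworked length correction. Counts of genes higher and lower stayed within 1.5 times their value in all comparisons and alternatives, from 2714 to 4056 and 2372 to 3354 in MUTZ-1 and 5232 to 5896 and 5194 to 6184 in SKM-1. The log2 fold change of NUDT21 ran from -1.12 to -1.05 and from -1.43 to -1.33. Counts of at least 2-fold changes moved more. In MUTZ-1 the 424 rises became 30 with log2(FPKM + 1), 243 with log2(FPKM + 0.1) and 231 at 1 CPM or more, and the 223 falls 32, 100 and 87, and 134 with only the 6 libraries compared. With log2(FPKM + 1), the SKM-1 counts of 1716 and 3064 became 864 and 1849, and the 2189 genes higher in control MUTZ-1 1315. A pseudocount shrinks the folds of low genes, and fewer genes are tested at 1 CPM, while the cause was not tested for the 6 libraries. Lists called higher and lower in MUTZ-1 (1 and 7) became 0 and 4 with an estimated correlation and 9 and 14 with fry. In SKM-1 (4 and 1) they became 2 and 0, and 13 and 13, with 2 lower with library totals. Between control lines (8 and 6) fry gave 15 and 13. For the difference between lines (0 and 2) fry gave 13 and 11, and 1 list higher, cytosolic ribosomal proteins (adjusted p = 0.0754), came with RLE (0.0494) and library totals (0.00149). Leaving out single libraries gave 0 to 1. The ribosomal protein list was called without any single MUTZ-1 library, and without SKM-1 knockdown replicate 1 or 2 (camera, adjusted p from 0.00956 to 0.0294). Oxidative phosphorylation genes were lower without SKM-1 knockdown replicate 3 (adjusted p = 0.0402, from 0.0754), and ribosomal proteins differed between control lines without MUTZ-1 control replicate 2 (0.0421, from 0.142) and with library totals (0.0184). The cause was not tested. Of 9637 values of named genes, 9491 kept direction and side of the threshold, 108 lost the call, 31 gained it and 7 changed sign, none of them called at first. These were differences between lines: CIITA (0.065 with log2(FPKM + 1)), KRT18 (-0.45), CLDN7 (-0.23, -0.17 with log2(FPKM + 0.1), -0.48 without MUTZ-1 knockdown replicate 2, against 2.75 without MUTZ-1 knockdown replicate 1) and CPSF6 (-0.083 with the length correction, -0.083 with the block added). With the turned sign, KRT18 (adjusted p = 5.36e-05 with log2(FPKM + 1)) and CPSF6 (adjusted p = 0.0216 with the length correction and 0.0234 with the block added) passed the threshold. For all of these sign changes the cause was not tested. In MUTZ-1, H2AC6 lost its call in 13 of 17 alternatives, LMO3 in 10 of 16 and CD247 in 7 of 17. Replicate numbers did not pair the libraries (correlations of same-numbered deviations -0.07 to 0.02, and not every library correlated best with its own number). With the replicate block, 3243 genes rose and 3290 fell in MUTZ-1 and 5706 and 5742 in SKM-1, and no list call changed. Depth limits folds of genes near 3 counts over a group, which are bounds.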

Other observations

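The genes of this paragraph and the sums over traces were chosen after their values had been seen, while the tests of long 3' untranslated regions and of neighbouring genes were fixed before. The SKM-1 libraries held globin mRNAs of embryonic and fetal type. In CPM without TMM scaling, HBE1 went from 1024 ± 15.5 to 1921 ± 32.2 from control to knockdown, HBG1 from 158 ± 11.1 to 605 ± 88.6, HBG2 from 328 ± 14.7 to 1274 ± 31.3 and HBZ from 134 ± 4.25 to 577 ± 47.0 (mean ± SD, n = 3), and HBG1 and HBG2 are near-identical copies. The monocyte marker CD14 stood at 0.117 and 0.122 CPM in these groups, while 8 and 10 of the 25 monocyte and macrophage markers reached 1 CPM in them.

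NUDT21 loss favours poly(A) sites close to the stop codon in other cells, so a hypothesis was that transcripts with long annotated 3' untranslated regions would be higher after knockdown. The median log2 change of the 25% of genes with the longest regions was compared with that of the 25% with the shortest. The difference, longest minus shortest, was 0.03 in MUTZ-1 (9541 genes) and -0.40 in SKM-1 (10541 genes). The rule set beforehand asked for at least 0.1 in both lines and was not met. Counts per gene sum reads along a transcript, so shorter 3' regions would themselves lower the counts of these genes. In SKM-1 a difference between subclones was not separated either. The test therefore cannot decide the hypothesis. Lengths of the sites in use were not measured.

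PTPRR (chromosome 12, positions 70638073 to 70920843, minus strand) and PTPRB (chromosome 12, positions 70515866 to 70637440, minus strand) lie 632 bases apart on the same strand and rose together in MUTZ-1. Transcription running on from an upstream gene into its downstream neighbour was a hypothesis, under which downstream neighbours of rising genes would exceed upstream ones. Within 10 kb of 219 rising genes, 39 downstream and 42 upstream neighbours had median log2 changes of 0.04 and 0.18, a difference of -0.14. The downstream median of 0.04 argues against run-on that lifts most downstream neighbours. Run-on at a minority of genes stays open, as does this gene pair. A median would miss it, and a downstream gene lifted at least 2-fold would place its source among the upstream neighbours.

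Genes of 1 line were found at traces in the other. Summed over 404 genes typical of SKM-1, MUTZ-1 control and knockdown libraries held 0.113% and 0.137% of the SKM-1 level, and over 63 genes typical of MUTZ-1, SKM-1 control and knockdown libraries held 0.170% and 0.119% of the MUTZ-1 level. Typical genes were those high in 1 line and under 1 CPM in both groups of the other. Low shares therefore follow from the choice of genes, and nothing is concluded from them.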
